A study of Mus musculus with 32 samples.

How the data were processed

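Sciatic nerves of mice aged 6 months were profiled by mRNA sequencing in 32 libraries of 4 genotypes. Per the labels' protocols, RNA was isolated with TRIzol and a column kit with DNase treatment, libraries were made with the KAPA mRNA HyperPrep kit after polyA selection, and paired reads were sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, reads were handled with Trim Galore, FastQC and RSEM against the mouse genome build GRCm38 (mm10). Versions of these tools, the aligner, its settings and the annotation release are not given in the sources used here. The deposited values are expected counts per gene and library, as the authors' table and its naming of RSEM state. They were whole numbers, so they had been rounded before deposit, and they were not scaled between libraries. The table held 45706 genes, of which 45143 carried a symbol, 563 did not and 19082 were never counted. Each column was assigned to its sample through the column letter in the sample's description, and genotype, sex and sample number were taken from the labels. As a check of that assignment, Xist and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were compared with the labelled sex.

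Genes were kept by edgeR's filterByExpr by genotype (minimum count 10, minimum total count 15), which left 15403 genes holding at least 99.7% of the counts of every library. Counts were scaled with TMM and fitted with edgeR's quasi-likelihood model on all 32 libraries with terms for genotype and labelled sex. The comparisons were each mutant against WT, the double mutant against C3-PMP22 and against Sipa1l2-/-, the interaction of transgene and Sipa1l2 genotype, and the interaction of transgene and sex. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Fold changes are given as log2 with their standard error (SE). For pooled contrasts, the mean of both transgenic genotypes was set against that of both others, and the mean of both Sipa1l2-/- genotypes against that of both others. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (1.17.8) were used, and gene positions and overlaps were taken from GENCODE M21.

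For each of 24 gene lists a score per library was computed as the mean over measured members of log2 CPM (prior count 2) centred on the mean of all libraries. Scores of groups were compared with an exact two-sided permutation test of the difference in means, with Benjamini-Hochberg adjustment over the lists of a comparison. For 8 against 7 libraries there are 6435 splits, and the smallest p is 0.000155. The lists covered cholesterol biosynthesis, fatty acid synthesis, myelin proteins and lipids, myelin transcription factors, repair and non-myelinating Schwann cells, cell cycle, macrophages, lymphocytes, cytokines and chemokines, and fibroblasts. They also covered basal lamina and matrix, perineurial cells, endothelial cells and pericytes, adipocytes, skeletal muscle, axonal and neuronal genes, erythrocytes, immediate early genes, ER stress, heat shock, mitochondrially encoded genes, neuropathy genes and the SIPA1 family. The SIPA1 family list also holds Rap GTPases and the regulators Rap1gap and Rap1gap2. As alternatives, limma's camera was run with a preset correlation of 0.01 between genes and with the correlation estimated from the data.

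The lists, comparisons, tests and naming rule were fixed before the data were examined. Of a fixed panel, Pmp22, Sipa1l2, Mbp, Egr2, Sox10, Jun and Ngfr are given in every comparison. In comparisons with calls, the 6 genes of each direction with the largest log2 fold change among those called, with a mean of at least 1 CPM and a symbol that is not a model name, were named, and up to 3 called members of each list with the smallest adjusted p. Without a call, the 3 genes with the smallest p were named. Some genes that the panel and these rules cover are not reported here, and counts of genes include them. Calls of the DESeq2 test alone, and the pooled contrasts, were named after their values were seen.

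Alternatives fixed beforehand were DESeq2's size factors in edgeR, total counts without composition scaling, the DESeq2 Wald test, no filter beyond 1 count, a mean of at least 1 CPM, no sex term, only the compared groups in the fit, the sample number as a block, and each library left out in turn. For scores, a prior count of 0.5, the median over members and removal of the mean of each sex were added to these. Chosen after seeing the data were robust estimation, sex from sex-linked genes, C3-PMP22 7 and 8 left out, terms for the animal-number series, the muscle score and the adipocyte score, and, for scores, single libraries left out, series means removed and the trend on the muscle score removed. Real counts were compared with those of 100 splits of the same libraries drawn at random, the real one included.

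The test was run on simulated data in which 200 of 15403 genes were changed by 1.5-fold, 2-fold or 4-fold. For C3-PMP22 against WT it recovered 41.8%, 73.1% and 97.0% of these, and 7 of 148 calls were false. For the double mutant it recovered 53.7%, 67.2% and 97.0% against WT, 50.7%, 77.6% and 90.9% against C3-PMP22 and 43.3%, 65.7% and 89.4% against Sipa1l2-/-. Simulated genes were drawn independently of each other, with the depth and spread of the real data. Structure that many genes share, such as muscle content, was thus absent, and rates in the real libraries may differ. Depth was 11030976 to 16990990 counts per library, and intervals of fold changes include both counting error and the spread between mice. All pairs of libraries within a genotype (113 pairs) differed by more than counting error, so no library was a copy of another of its genotype. The lowest chi-square was 12.4 per gene, between C3-PMP22 7 and 8. Separate samples of the same animal are not excluded by this. Pairs across genotypes were not compared. No library was left out of the primary results, and transcript-level or splice-level values were not analysed here.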

Results

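Polyadenylated RNA from the sciatic nerve of 32 mice aged 6 months was sequenced to ask how a PMP22 transgene and the loss of Sipa1l2, alone and together, alter the transcripts of the nerve. C3-PMP22 mice carry the human PMP22 gene, which encodes a protein of compact peripheral myelin, and serve as a model of Charcot-Marie-Tooth disease type 1A, the demyelinating neuropathy caused by duplication of that gene. Sipa1l2 encodes a GTPase-activating protein of the SIPA1 family, which acts on Rap GTPases, and the series names it as a modifier of the disease. The groups were wild type (WT, n = 7, 4 labelled female and 3 male), Sipa1l2-/- (n = 9, 4 female and 5 male), C3-PMP22 (n = 8, 4 female and 4 male) and C3-PMP22 Sipa1l2-/-, called the double mutant here (n = 8, 5 female and 3 male). Each library came from a separately numbered sample, and p-values of comparisons between groups refer to the spread between these samples. Fisher's and hypergeometric tests and the scan of gene positions count genes or labels instead.

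Total counts per library lay between 11030976 and 16990990, with a median of 13260300 over all libraries. The group medians were 13091641 in WT, 13253239 in Sipa1l2-/-, 12810287 in C3-PMP22 and 13520300 in the double mutant. Of 45706 genes in the table, 15403 passed the low-count filter and were tested. At this depth and number of mice, the 95% confidence interval of a log2 fold change between C3-PMP22 and WT had a median half-width of 0.32. In the column headers, identifiers of 19 libraries were plain numbers and those of 13 carried a leading G. These are treated as 2 series of animal numbers, since all 5 female double mutants belonged to the plain series and all 3 male double mutants to the G series, while the other genotypes held both series in each sex. Differences of the double mutant within a series are therefore also differences in the share of each sex. Several identifiers within a series shared their leading part, whose meaning is not given. All libraries were treated as independent.

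Transcripts of the Sipa1l2 gene itself (ENSMUSG00000001995, GRCm38 chromosome 8, 125418063 to 125569808) were not lower in the libraries labelled Sipa1l2-/- over both sexes. Mean counts-per-million (CPM) were 82.9 ± 20.3 (SD, n = 7) in WT, 88.9 ± 28.6 (n = 9) in Sipa1l2-/-, 90.1 ± 25.4 (n = 8) in C3-PMP22 and 86.0 ± 40.7 (n = 8) in the double mutant. The log2 fold change of Sipa1l2-/- against WT was 0.05 (95% confidence interval -0.43 to 0.53), and that of the double mutant against C3-PMP22 was -0.10 (-0.57 to 0.37). The latter joins opposite directions, with 5.84 ± 0.32 log2 CPM (SD, n = 5) in female double mutants against 6.52 ± 0.52 (n = 4) in females labelled C3-PMP22, and 7.03 ± 0.23 (n = 3) against 6.38 ± 0.30 (n = 4) in males. Over both backgrounds, libraries labelled Sipa1l2-/- held 0.983 times the Sipa1l2 counts of those with an intact gene (95% confidence interval 0.779 to 1.24). Genotypes below are therefore those of the labels. Mouse Pmp22 (ENSMUSG00000018217, chromosome 11, 63128982 to 63159547) had means of 3306 ± 950.0 CPM (SD, n = 7) in WT, 3316 ± 1132 (n = 9) in Sipa1l2-/-, 2849 ± 757.5 (n = 8) in C3-PMP22 and 2180 ± 1392 (n = 8) in the double mutant. The table is organised by mouse gene, and whether reads of the human transgene entered the Pmp22 counts is not given in the sources used here.

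**Figure D1:**
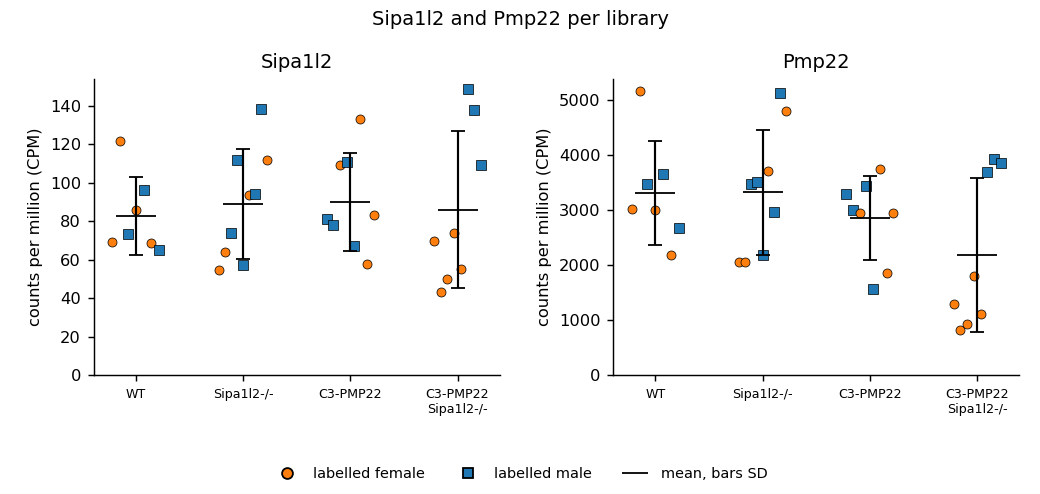
Sipa1l2 and Pmp22 counts-per-million (linear vertical axes starting at 0) in each library by genotype, marked by labelled sex, with the group mean and bars of 1 SD. The Sipa1l2 means lie between 82.9 and 90.1 CPM in the 4 genotypes.

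Sex-linked transcripts matched the labelled sex in 30 of 32 libraries. Xist, the RNA of the inactive X chromosome, lay between 888.3 and 1466 CPM in the matching libraries labelled female and at most at 0.964 CPM in those labelled male. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y lay at medians of 107.6, 26.7, 30.3 and 55.4 CPM in libraries labelled male and at most at 0.149 CPM in the matching female ones. C3-PMP22 libraries 7 and 8 were labelled female, but held 0.109 and 0.366 CPM of Xist and 146.6 and 146.2 CPM of Ddx3y. Uty was at 32.8 and 33.6 CPM, Kdm5d at 27.4 and 36.0 CPM and Eif2s3y at 71.2 and 85.7 CPM in these libraries. Labels were kept as given, and calls of genes named here that ended without both libraries are stated.

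**Figure D2:**
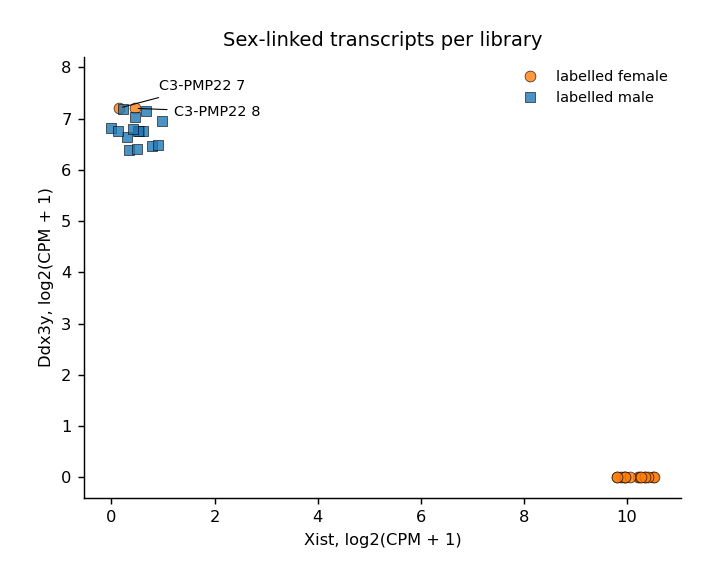
Ddx3y (vertical axis) over Xist (horizontal axis), each as log2 of CPM plus 1, in the 32 libraries, marked by labelled sex. C3-PMP22 libraries 7 and 8, labelled female, lie with the libraries labelled male.

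Skeletal muscle transcripts varied widely within every genotype. Acta1, the alpha-actin of skeletal muscle, lay between 0.575 and 19444 CPM, with medians of 455.5 CPM in WT, 572.2 in Sipa1l2-/-, 4420.2 in C3-PMP22 and 4154 in the double mutant. The highest values were those of C3-PMP22 7 and 8, at 19444 and 18057 CPM. The skeletal muscle list score, a mean centred log2 CPM over 15 genes, was 0.82 ± 4.13 (SD, n = 8) in C3-PMP22, 1.03 ± 3.55 (n = 8) in the double mutant, -1.17 ± 4.64 (n = 9) in Sipa1l2-/- and -0.61 ± 2.75 (n = 7) in WT. The exact permutation test gave adjusted p = 0.759 for C3-PMP22, 0.499 for the double mutant and 0.99 for Sipa1l2-/- against WT. Muscle content was the largest measured source of variation between libraries. In a principal component analysis of log2 CPM, component 1 held 41.0% of the variance and correlated with the muscle score at 0.96. Component 2 held 11.8% and correlated with the myelin score at -0.85 and the adipocyte score at 0.73.

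C3-PMP22 nerves were compared with WT nerves to measure the effect of the transgene without the Sipa1l2-/- label. Among called genes with a mean of at least 1 CPM, and apart from Ddx3y, the largest increases were in Piwil4, an Argonaute-family protein of the piRNA pathway (ENSMUSG00000036912, chromosome 9), and Ankrd63, an ankyrin repeat protein (ENSMUSG00000078137, chromosome 2). Piwil4 rose from 0.446 ± 0.134 CPM (SD, n = 7) to 5.89 ± 2.04 CPM (n = 8), a log2 fold change of 3.73 ± 0.49 (SE, adjusted p = 7.24e-05). Ankrd63 rose from 0.686 ± 0.209 to 6.35 ± 3.14 CPM (log2 fold change 3.18 ± 0.39, adjusted p = 3.92e-05). Btbd16 (2.98 ± 0.49), the phosphatase regulatory subunit Ppp2r2c (2.34 ± 0.39) and the extracellular matrix protein Emid1 (2.34 ± 0.37) rose as well, with adjusted p between 0.000826 and 0.00125. Above the same mean, the largest decreases were in the cytochrome P450 gene Cyp2j13 (-2.65 ± 0.54, adjusted p = 0.00959) and the transcription factor gene Wt1 (-2.46 ± 0.40, adjusted p = 0.00109). Trichohyalin (Tchh, -2.33 ± 0.32, adjusted p = 8.74e-05), the presynaptic active-zone gene Erc2 (-2.21 ± 0.48, adjusted p = 0.0166), Tmem28 (-2.14 ± 0.28, adjusted p = 6.81e-05) and Fam110c (-2.07 ± 0.47, adjusted p = 0.0241) fell too. Each of these genes lay on that side of the WT mean in 8 of 8 C3-PMP22 libraries. Ddx3y had a log2 fold change of 6.42 ± 1.56 (adjusted p = 0.0439) that came from the labels of C3-PMP22 7 and 8, and without both it was -0.05. In the annotation Btbd16 overlaps Fgfr2 on the other strand, so its counts are less certain.

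Cholesterol biosynthesis transcripts fell together in C3-PMP22 nerves. All 24 members of the list had negative log2 fold changes, 8 fell at adjusted p under 0.05 over all genes, and 24 did so when adjusted over the list alone. The log2 fold change was -0.58 ± 0.11 for mevalonate kinase (Mvk, SE, adjusted p = 0.00755) and -0.95 ± 0.19 for squalene epoxidase (Sqle, adjusted p = 0.00959). The list score was -0.28 ± 0.22 (SD, n = 8) in C3-PMP22 and 0.35 ± 0.18 (n = 7) in WT (exact two-sided permutation p = 0.000155, the smallest that 6435 splits allow). Its adjusted p over 24 lists was 0.00373, and adjusted p = 0.00693 with an estimated correlation. The difference was -0.55 within the plain series (4 against 3, exact p = 0.0286) and -0.72 within the G series (4 against 4, exact p = 0.0286), and -0.59 without C3-PMP22 7 and 8 (adjusted p = 0.0140). Fatty acid synthesis genes did not pass as a list (-0.28 ± 0.36 against 0.15 ± 0.52, adjusted p = 0.244), and 0 of 18 members were called.

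Genes of the repair Schwann cell, the state that Schwann cells take up after nerve injury, scored 0.29 ± 0.20 (SD, n = 8) in C3-PMP22 against -0.14 ± 0.21 (n = 7) in WT. The exact permutation p was 0.00249 and its adjusted p 0.0298, but adjusted p = 0.195 with an estimated correlation. Of 18 measured members, 2 rose over all genes and 8 rose and 1 fell when adjusted over the list alone. Gfap, an intermediate filament of non-myelinating and repair Schwann cells, rose by 1.47 ± 0.30 (SE, adjusted p = 0.0107), and the transcription factor Sox4 rose by 0.66 ± 0.15 (adjusted p = 0.0217). The score difference was 0.45 within the plain series (4 against 3, exact p = 0.0286) and 0.39 within the G series (4 against 4, exact p = 0.0571). The call ended without WT 1 or any of C3-PMP22 1, 3, 4 and 6, where adjusted p lay between 0.0519 and 0.0559. It also ended with libraries scaled by total counts alone (difference 0.27, adjusted p = 0.325), with members of at least 1 CPM (adjusted p = 0.0839) and with series means removed (adjusted p = 0.0914). Of 14 non-myelinating Schwann cell genes 2 rose, Gfap and Apod, which encodes the lipid carrier apolipoprotein D (0.93 ± 0.18, adjusted p = 0.00718), and 5 rose when adjusted over the list alone (list adjusted p = 0.186).

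Among 23 macrophage genes, 2 rose in C3-PMP22 nerves and 4 rose when adjusted over the list alone. The fractalkine receptor gene Cx3cr1 rose by 1.58 ± 0.26 (SE, adjusted p = 0.00107) and the lipid-sensing receptor gene Trem2 by 1.04 ± 0.21 (adjusted p = 0.00929), while the list score did not pass (0.05 ± 0.41 against -0.19 ± 0.23, adjusted p = 0.413). The annotation of Cx3cr1 spans several other genes, which makes its counts less certain. Myelin protein and lipid genes scored 0.19 ± 0.38 (SD, n = 8) against 0.11 ± 0.36 (n = 7; adjusted p = 0.899), and 1 of 26 rose, the membrane scaffold gene Mpp6 (0.76 ± 0.17, adjusted p = 0.0217), which overlaps Gsdme on the other strand. Mbp had a log2 fold change of -0.14 ± 0.29 (SE, adjusted p = 0.819) and Pmp22 -0.25 ± 0.29 (0.667). The myelin transcription factors Egr2 and Sox10 had 0.21 ± 0.35 (0.768) and -0.02 ± 0.33 (0.976). The injury-response genes Jun and Ngfr had 0.18 ± 0.14 (0.472) and 0.69 ± 0.25 (0.166), and Sipa1l2 0.10 ± 0.24 (0.84). Of 13 axonal and neuronal genes 1 fell, the gamma-synuclein gene Sncg (-0.91 ± 0.21, adjusted p = 0.0309), and 1 rose and 2 fell when adjusted over the list alone (list adjusted p = 0.186).

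No other list passed between C3-PMP22 and WT. Endothelial cell and pericyte genes had a score difference of -0.38 (exact p = 0.0174, adjusted p = 0.139), with 0 of 16 called and 7 lower when adjusted over the list alone. Basal lamina and matrix genes had -0.17 (adjusted p = 0.348, 0 called, 4 lower over the list alone), adipocyte genes -0.71 (0.206) and lymphocyte genes -0.45 (0.348). The 13 mitochondrially encoded genes had 0.71 (adjusted p = 0.206), with 0 called and 13 higher when adjusted over the list alone. Differences were 0.18 for myelin transcription factors (0.244), 0.01 for cell cycle genes (0.975), -0.01 for cytokines and chemokines (0.975) and -0.10 for fibroblast genes (0.823). They were 0.02 for perineurial cell genes (0.975), -0.41 for erythrocyte genes (0.823), -0.08 for immediate early genes (0.958) and 0.05 for ER stress genes (0.695). Heat shock genes had -0.00 (0.975), neuropathy genes 0.07 (0.823) and SIPA1 family genes 0.03 (0.932).

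By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 106 of 15403 genes differed between C3-PMP22 and WT, 58 higher and 48 lower, and 50 of them by at least 2-fold. DESeq2 called 375. The share of higher genes among calls was 54.7%, but 41.3% with DESeq2's size factors in edgeR (57 higher, 81 lower), 43.7% with DESeq2 and 27.8% with total counts alone (30 higher, 78 lower), where the median log2 fold change of all genes moved from 0.04 to -0.12. The count was 58 without C3-PMP22 7 and 8, and it was 410 without WT 3, 183 without C3-PMP22 2 and 233 without C3-PMP22 5. Without C3-PMP22 7 and 8, 52 of the 106 calls were kept and 105 had the same sign, and adjusted p was 0.0609 for Gfap and Sqle, 0.0942 for Erc2, 0.125 for Fam110c, 0.150 for Sncg and 0.192 for Mpp6. Leaving out 1 library also ended some calls. The adjusted p of Fam110c lay between 0.0517 and 0.0844 without any 1 of C3-PMP22 3, 4, 7, 8 or WT 4, 5, 6, 7. That of Mpp6 lay between 0.0579 and 0.0698 without WT 4, 5, 6 or C3-PMP22 7, 8. Sox4 lay between 0.0507 and 0.0731 without C3-PMP22 4, 6 or WT 4, 5. Sncg lay between 0.0524 and 0.0881 without C3-PMP22 1, 3, 4, 7, 8 or WT 2, 4, 5, 6. Ddx3y lay between 0.0501 and 0.11 in 23 of the 32 fits, and kept its call without C3-PMP22 1, 2, 3, 4, 5, 6, WT 3, Sipa1l2-/- 3 or double mutant 8. With total counts alone adjusted p was 0.0786 for Trem2, 0.0813 for Apod and 0.167 for Sox4, and with only the compared groups in the fit it was 0.0676, 0.0656 and 0.107. Of 21 settings other than single libraries, these 3 genes kept their calls in 19, Erc2 in 18, Mpp6 in 17, Sncg in 13, Fam110c in 11 and Ddx3y in 4.

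Sipa1l2-/- nerves were compared with WT nerves to ask whether transcripts differ with the Sipa1l2-/- label in the absence of the transgene, and no gene passed. The smallest p-values belonged to Slc1a4, a neutral amino acid transporter (log2 fold change -1.02 ± 0.24, SE, n = 9 and 7, adjusted p = 0.839 by edgeR), the kallikrein Klk1 (-1.83 ± 0.44) and Rmc1 (-0.48 ± 0.12), a regulator of late endosomes whose annotation overlaps Npc1 on the other strand. Pmp22 had a log2 fold change of -0.06 ± 0.29, Mbp -0.01 ± 0.28, Egr2 -0.03 ± 0.34 and Sox10 -0.21 ± 0.33, with adjusted p of at least 0.968 by edgeR. Jun had 0.01 ± 0.13 and Ngfr 0.11 ± 0.24, with adjusted p of at least 0.978. All 24 cholesterol biosynthesis genes had negative log2 fold changes, 0 were called and 1 was lower when adjusted over the list alone. Their score was 0.13 ± 0.14 (SD, n = 9) against 0.35 ± 0.18 (n = 7; exact permutation p = 0.0173, adjusted p = 0.415), with differences of -0.27 within the plain series (7 against 3, exact p = 0.0417) and -0.13 within the G series (2 against 4, exact p = 0.40). Myelin genes scored 0.05 ± 0.48 against 0.11 ± 0.36 (adjusted p = 0.99), repair Schwann cell genes -0.29 ± 0.20 against -0.14 ± 0.21 (0.757) and macrophage genes -0.11 ± 0.35 against -0.19 ± 0.23 (0.99). No list passed. The edgeR quasi-likelihood test called 0 genes, with 803 at unadjusted p under 0.05 and a smallest adjusted p of 0.839, and DESeq2 also called 0. In simulated data with these libraries, the same test recovered 55.2% of genes changed 1.5-fold, 77.6% of genes changed 2-fold and 95.5% of genes changed 4-fold. Genes were drawn independently there, so structure shared by many genes was absent.

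Double mutant nerves were compared with WT nerves for the joint effect of the transgene and the Sipa1l2-/- genotype. Piwil4 rose by 3.61 ± 0.50 on the log2 scale (SE, n = 8 and 7, edgeR adjusted p = 0.000234) and Ankrd63 by 3.27 ± 0.39 (adjusted p = 4.58e-05). Clca3a2, of the chloride channel accessory family (2.70 ± 0.48), Btbd16 (2.29 ± 0.50), the neuronal tubulin Tubb3 (2.17 ± 0.44) and the glial potassium channel Kcnj10 (2.01 ± 0.37) rose with adjusted p between 0.00268 and 0.0136. Tubb3 overlaps the readthrough gene Gm20388 on the same strand. Cyp2j13 (-3.26 ± 0.56, adjusted p = 0.00194), Wt1 (-3.09 ± 0.42, adjusted p = 0.000234), Erc2 (-2.52 ± 0.48, adjusted p = 0.00483) and Tchh (-2.16 ± 0.31, adjusted p = 0.000295) fell. The imprinted gene Mest (-2.73 ± 0.62, adjusted p = 0.0206), which overlaps Copg2 on the other strand, and the complement component C6 (-2.49 ± 0.64, adjusted p = 0.0435) fell as well. Each lay on that side of the WT mean in 8 of 8 double mutant libraries, except Btbd16 in 7.

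Cholesterol biosynthesis transcripts were also lower in double mutant than in WT nerves, at -0.18 ± 0.29 (SD, n = 8) against 0.35 ± 0.18 (n = 7). The exact permutation p was 0.00171 and its adjusted p 0.0410, and adjusted p = 0.0525 with an estimated correlation. All 24 genes had negative log2 fold changes, 7 fell, and 17 fell when adjusted over the list alone. Sqle was among those that fell (-0.92 ± 0.19, SE, adjusted p = 0.00917). The difference was -0.59 within the plain series (5 against 3, exact p = 0.0714) and -0.45 within the G series (3 against 4, exact p = 0.0286). The call ended without any 1 of double mutants 1, 2, 3, 4, 6, 8 or WT 2, 4, 5, 6, 7, with adjusted p between 0.0559 and 0.0839. The 13 mitochondrially encoded genes scored 0.27 ± 0.26 (SD, n = 8) against -0.44 ± 0.44 (n = 7; exact p = 0.00388, adjusted p = 0.0466, and adjusted p = 0.328 with an estimated correlation). Of these genes 0 were called and 4 were higher when adjusted over the list alone. The difference was 0.39 within the plain series (5 against 3, exact p = 0.107) and 0.90 within the G series (3 against 4, exact p = 0.0286), and 0.51 with the trend on the muscle score removed (adjusted p = 0.0522). That call ended without any 1 of double mutants 1, 2, 3, 4, 5, 6, 8 or WT 2, 4, 5, 6, 7, with adjusted p between 0.0613 and 0.105.

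Macrophage genes in double mutants included 3 of 23 that rose, and 5 when adjusted over the list alone. Cx3cr1 rose by 1.76 ± 0.26 (SE, adjusted p = 0.000295), Trem2 by 0.94 ± 0.21 (adjusted p = 0.0157) and Aif1, the gene of the macrophage marker IBA1, by 0.77 ± 0.20 (adjusted p = 0.0432). Their score was 0.24 ± 0.39 (SD, n = 8) against -0.19 ± 0.23 (n = 7; adjusted exact p = 0.154), with differences of 0.81 within the plain series (5 against 3, exact p = 0.0179) and -0.07 within the G series (3 against 4, exact p = 0.657). Of 17 cytokine and chemokine genes 1 rose, the chemokine gene Cxcl10 (1.29 ± 0.34, adjusted p = 0.0492), which overlaps Art3 on the other strand, and 2 rose over the list alone (list adjusted p = 0.176). Of 18 repair Schwann cell genes 1 rose, Sox4 (0.85 ± 0.15, adjusted p = 0.00194), and 5 rose and 1 fell when adjusted over the list alone (score difference 0.29, adjusted p = 0.195). That difference was 0.03 within the plain series (5 against 3, exact p = 0.857) and 0.68 within the G series (3 against 4, exact p = 0.0286). Apod rose by 0.77 ± 0.18 (adjusted p = 0.0236), 1 of 14 non-myelinating Schwann cell genes, with 2 higher over the list alone (list adjusted p = 0.640). Cell cycle genes had a score difference of 0.32 (adjusted p = 0.0995, 0 of 32 called), and passed with the mean of each sex removed (0.31, adjusted p = 0.0435) but not with an estimated correlation (adjusted p = 0.328).

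Matrix and axonal genes fell in part. Lysyl oxidase (Lox, -0.89 ± 0.18, SE, adjusted p = 0.00737) and the collagen gene Col4a2 (-0.82 ± 0.21, adjusted p = 0.0408), which overlaps Col4a1 on the other strand, were the 2 of 26 basal lamina and matrix genes that fell, with 5 lower over the list alone (list adjusted p = 0.176). Of 13 axonal and neuronal genes Sncg fell (-1.16 ± 0.21, adjusted p = 0.00291) and Tubb3 rose, and 8 fell and 1 rose when adjusted over the list alone. The axonal score was -0.33 ± 0.55 (SD, n = 8) against 0.16 ± 0.22 (n = 7; adjusted exact p = 0.176), with differences of -0.94 within the plain series (5 against 3, exact p = 0.0179) and 0.18 within the G series (3 against 4, exact p = 0.286). Myelin genes scored -0.34 ± 0.87 against 0.11 ± 0.36 (adjusted p = 0.423), with 0 of 26 called. This value joins opposite directions, a difference of -1.24 within the plain series (5 against 3, exact p = 0.0179, the smallest possible there) and 0.69 within the G series (3 against 4, exact p = 0.0571). Pmp22 had a log2 fold change of -0.71 ± 0.30 (SE, adjusted p = 0.245) and Mbp -0.46 ± 0.29 (0.489). Egr2 had -0.27 ± 0.35 (0.790), Sox10 -0.39 ± 0.34 (0.644), Jun 0.34 ± 0.14 (0.230), Ngfr 0.53 ± 0.25 (0.309) and Sipa1l2 0.01 ± 0.24 (0.994). With muscle and adipocyte score terms in the fit, Pmp22 (-1.03, adjusted p = 0.00313) and Mbp (-0.78, adjusted p = 0.0131) were called.

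By edgeR's test 213 genes differed between double mutant and WT nerves, 80 higher and 133 lower, and 83 of them by at least 2-fold. DESeq2 called 499, and edgeR called 118 with total counts alone and 134 without a sex term. It called many more with muscle and adipocyte score terms, as given below. The count was 120 without WT 4, 115 without WT 5, 111 without WT 6, 126 without double mutant 2 and 141 without double mutant 8. The adjusted p of Mest was 0.0904 without WT 4, and that of Apod lay between 0.0511 and 0.0665 without double mutant 6, WT 4 or WT 6. That of C6 lay between 0.0501 and 0.198 without any 1 of the 8 double mutants, WT 4, 5, 6, 7, C3-PMP22 3, 4 or Sipa1l2-/- 4. Aif1 lay between 0.0502 and 0.106 without double mutants 2, 3, 4, 5, 6, 8, WT 2, 3, 4, 5, 6, C3-PMP22 3, 4, 7 or Sipa1l2-/- 6. Col4a2 lay between 0.0529 and 0.0988 without double mutants 1, 2, 3, 4, 6, 7, 8 or WT 2, 4, 5, 6, 7. Cxcl10 lay between 0.0505 and 0.119 in 22 of the 32 fits, and kept its call without WT 2, 4, Sipa1l2-/- 1, 2, 3, 7, 8, 9, C3-PMP22 5 or double mutant 5. Without C3-PMP22 7 and 8 the adjusted p of Cxcl10 was 0.0532. Of 21 settings other than single libraries, C6 kept its call in 9, and it ended without a sex term, with total counts alone, with no filter beyond 1 count, with the sample number as a block, with sex from sex-linked genes, and with series or muscle terms. Aif1 and Cxcl10 kept theirs in 13, Col4a2 in 14, Mest and Apod in 19, and Btbd16 and Trem2 in 20.

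**Figure D3:**
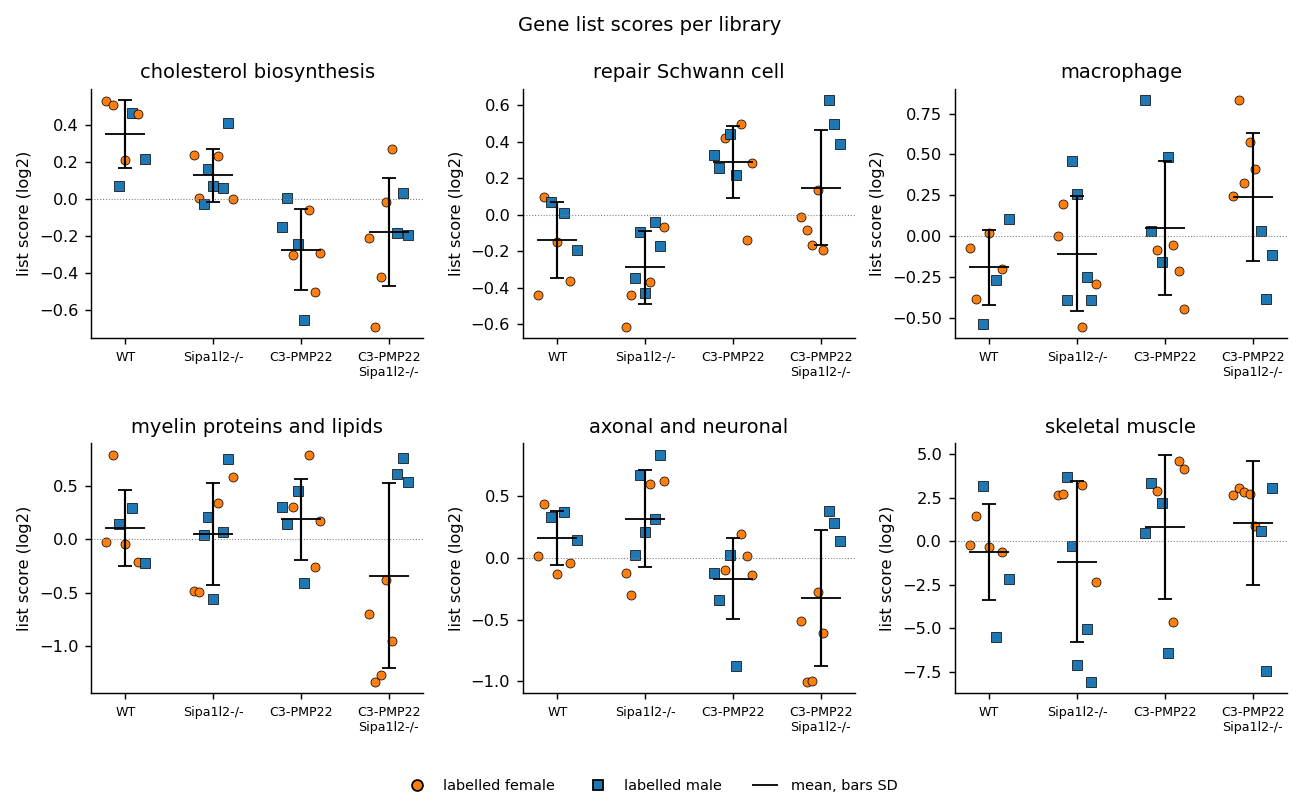
List scores (mean centred log2 counts-per-million, vertical axis) of selected gene lists in each library by genotype, marked by labelled sex, with the group mean and bars of 1 SD. Cholesterol biosynthesis scores average 0.35 in WT, 0.13 in Sipa1l2-/-, -0.28 in C3-PMP22 and -0.18 in the double mutant.

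Double mutant nerves were compared with Sipa1l2-/- nerves to measure the transgene's effect on the Sipa1l2-/- background. Piwil4 rose by 3.86 ± 0.46 on the log2 scale (SE, n = 8 and 9, edgeR adjusted p = 1.72e-05) and Ankrd63 by 3.62 ± 0.37 (adjusted p = 1.16e-06). Clca3a2 (2.60 ± 0.44), Emid1 (2.20 ± 0.34), the muscarinic receptor gene Chrm1 (2.18 ± 0.37) and Ppp2r2c (2.15 ± 0.36) rose with adjusted p between 0.000382 and 0.000978. Cyp2j13 (-3.68 ± 0.54), Wt1 (-3.06 ± 0.41), Tchh (-2.18 ± 0.30), the imprinted gene Dlk1 (-2.13 ± 0.33) and the crystallin gene Crygs (-1.91 ± 0.31) fell with adjusted p between 9.34e-05 and 0.000622, and Erc2 fell by 2.35 ± 0.47 (adjusted p = 0.00738). Of 18 repair Schwann cell genes 4 rose and 8 rose when adjusted over the list alone, among them Sox4 (1.14 ± 0.14, adjusted p = 1.72e-05), Gfap (1.55 ± 0.28, adjusted p = 0.00283) and Btc, which encodes the growth factor betacellulin (1.25 ± 0.28, adjusted p = 0.0232). Their score was 0.15 ± 0.32 (SD, n = 8) against -0.29 ± 0.20 (n = 9; exact permutation p = 0.00321, adjusted p = 0.0770, and adjusted p = 0.00705 with an estimated correlation). Its adjusted p was 0.0336 with a prior count of 0.5, 0.00889 with the mean of each sex removed, 0.0247 with series means removed and 0.0464 with the trend on the muscle score removed. The difference was 0.27 within the plain series (5 against 7, exact p = 0.0316) and 0.63 within the G series (3 against 2, exact p = 0.10, the smallest possible there).

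Cholesterol biosynthesis and axonal genes were lower in parts of their lists. Of 24 cholesterol genes 3 fell and 8 fell when adjusted over the list alone, with Hsd17b7 at -0.89 ± 0.19 (SE, adjusted p = 0.0135) and the sterol transporter gene Stard4 at -0.60 ± 0.14 (adjusted p = 0.0322). Their score was -0.18 ± 0.29 (SD, n = 8) against 0.13 ± 0.14 (n = 9; exact p = 0.0116, adjusted p = 0.0898), with -0.32 within the plain series (5 against 7, exact p = 0.0467) and -0.32 within the G series (3 against 2, exact p = 0.30). The neurofilament genes Nefh (-1.50 ± 0.34, adjusted p = 0.0219) and Nefm (-1.29 ± 0.32, adjusted p = 0.0483), the latter overlapping Nefl on the other strand, were the 2 of 13 axonal genes that fell, with 10 lower and 1 higher over the list alone. The axonal score was -0.33 ± 0.55 against 0.32 ± 0.39 (exact permutation p = 0.0150, adjusted p = 0.0898, adjusted p = 0.0415 with series means removed, and adjusted p = 0.0504 with an estimated correlation), with -0.88 within the plain series (5 against 7, exact p = 0.00379) and -0.46 within the G series (3 against 2, exact p = 0.10). Cx3cr1 (1.47 ± 0.24, adjusted p = 0.000562) and Trem2 (1.07 ± 0.20, adjusted p = 0.00283) were the 2 of 23 macrophage genes that rose, with 4 over the list alone (list adjusted p = 0.308). Cxcl10 rose by 1.34 ± 0.32 (adjusted p = 0.0322), 1 of 17 cytokine genes (list adjusted p = 0.571), and Lox had -0.79 ± 0.17 (adjusted p = 0.0163), the 1 of 26 matrix genes that fell (list adjusted p = 0.571). Gfap was also the 1 of 14 non-myelinating Schwann cell genes that rose (list adjusted p = 0.627), and cell cycle genes had a score difference of 0.36 (adjusted p = 0.0898, 0 of 32 called).

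None of the panel genes named here passed between double mutant and Sipa1l2-/- nerves by edgeR. Pmp22 had a log2 fold change of -0.64 ± 0.28 (SE, n = 8 and 9, adjusted p = 0.448) and Mbp -0.45 ± 0.27 (0.726). Egr2 had -0.24 ± 0.33, Sox10 -0.18 ± 0.31, Sipa1l2 -0.04 ± 0.22, Jun 0.33 ± 0.13 and Ngfr 0.42 ± 0.23, with adjusted p of at least 0.376. The test called 111 genes, 57 higher and 54 lower, 84 of them by at least 2-fold, and DESeq2 called 219. The adjusted p of Btc was 0.0621 and that of Nefh 0.0804 without Sipa1l2-/- 6. Stard4 lay between 0.0557 and 0.0831 without Sipa1l2-/- 1, 6, 8, 9 or double mutants 1, 2, 3, 5, and Cxcl10 between 0.0554 and 0.10 without Sipa1l2-/- 1, 2, 3, 6, 7 or double mutants 1, 2, 6. Nefm lay between 0.0507 and 0.116 in 22 of the 32 fits, and kept its call without WT 2, 4, Sipa1l2-/- 2, 3, 5, C3-PMP22 2, 5, 7 or double mutants 7, 8. Of 21 settings other than single libraries, Nefm kept its call in 15, Stard4 in 16, Btc in 17, Cxcl10, Lox and Nefh in 19 and Erc2 in 20. No list passed with all libraries, while 2 passed without Sipa1l2-/- 4 and 2 without double mutant 5.

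Both measures of the transgene effect share no library, so their calls can be set against each other. The C3-PMP22 against WT and double mutant against Sipa1l2-/- comparisons shared 29 higher genes where 0.215 would be expected by chance (Fisher's exact p = 1.41e-58) and 19 lower genes where 0.168 would be (Fisher's exact p = 6.67e-36). Piwil4, Ankrd63, Emid1, Ppp2r2c, Gfap, Sox4, Cx3cr1 and Trem2 were among the shared higher genes, and Wt1, Cyp2j13, Tchh, Erc2, Tmem28, Dlk1 and Stard4 among the shared lower ones. Fisher's test treats genes as independent, and both comparisons came from the same fit, so its p-values do not measure replication between mice. No gene was called in opposite directions. Of the 106 calls in C3-PMP22, 100 had the same sign in the other comparison, and of the 111 calls there 110 had the same sign in C3-PMP22, against 56.6% of all genes tested. Ankrd63 lay between 2.27 and 10.4 CPM in the 16 transgenic libraries and at most at 1.18 CPM in the 16 others. Piwil4 lay between 1.41 and 18.9 CPM and at most at 0.718 CPM.

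**Figure D4:**
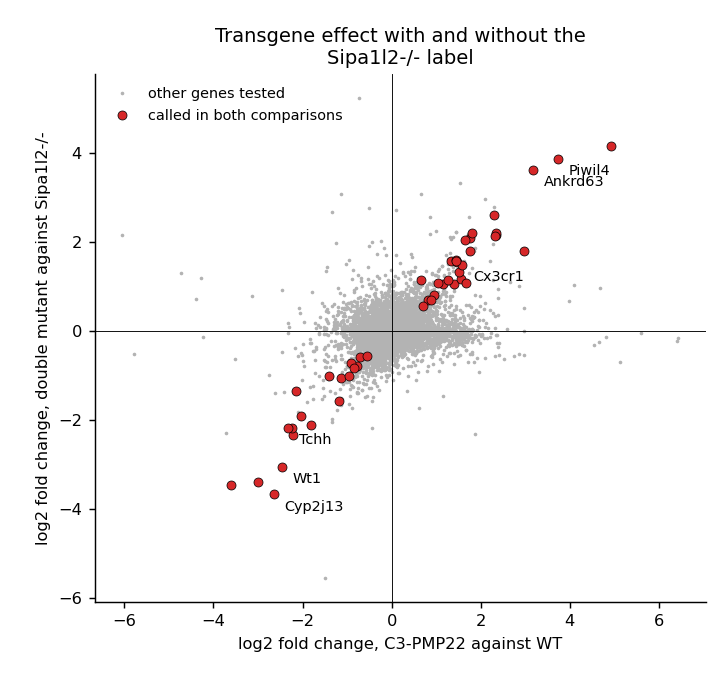
Log2 fold change of double mutant against Sipa1l2-/- nerves (vertical axis) over that of C3-PMP22 against WT nerves (horizontal axis) for the tested genes, with genes called in both comparisons marked. The 48 genes called in both lie in the quadrants of equal sign.

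Double mutant nerves were compared with C3-PMP22 nerves to ask whether the Sipa1l2-/- genotype alters transcripts in the presence of the transgene. The smallest p-values belonged to Rab4a, a GTPase of endosomal recycling (log2 fold change -0.66 ± 0.15, SE, n = 8 and 8, edgeR adjusted p = 0.601), to Mgp, which encodes the matrix Gla protein that restrains calcification (0.66 ± 0.15), and to Ddx3y (-6.52 ± 1.49), which follows from C3-PMP22 7 and 8. Rab4a (chromosome 8, 123805985 to 123835287) lies near Sipa1l2 and overlaps the readthrough gene Gm20388 on the same strand. Pmp22 had a log2 fold change of -0.46 ± 0.28, Mbp -0.32 ± 0.28, Egr2 -0.48 ± 0.35 and Sox10 -0.37 ± 0.32, with edgeR adjusted p between 0.620 and 0.683. Jun had 0.16 ± 0.13 and Ngfr -0.16 ± 0.24, with adjusted p between 0.668 and 0.797. Cholesterol genes scored -0.18 ± 0.29 (SD, n = 8) against -0.28 ± 0.22 (n = 8; adjusted exact p = 0.647) and repair Schwann cell genes 0.15 ± 0.32 against 0.29 ± 0.20 (0.60). Myelin genes scored -0.34 ± 0.87 against 0.19 ± 0.38 (adjusted exact p = 0.407), with all 26 log2 fold changes negative and 0 called. Within the plain series the myelin difference was -1.24 (5 against 4, exact p = 0.00794, the smallest possible there), and within the G series it was 0.57 (3 against 4, exact p = 0.20), so the pooled value joins opposite directions. Sex was not balanced within the series. Of the 4 plain C3-PMP22 libraries 1 was labelled female, against all 5 plain double mutants. Of the 4 G ones 1 was labelled male, against all 3 G double mutants. C3-PMP22 7 and 8 were among those 4 and carried Y-linked transcripts under female labels, so the imbalance by transcripts was smaller there. Differences within the plain series were also -0.53 for non-myelinating (exact p = 0.00794) and -0.43 for repair Schwann cell genes (exact p = 0.0159) and -0.34 for the SIPA1 family (exact p = 0.00794), and those within the G series were 0.36, 0.29 and 0.22 (exact p between 0.143 and 0.286). Myelin transcription factors had -0.49 (exact p = 0.00794), neuropathy genes -0.61 (exact p = 0.0159) and axonal genes -0.54 (exact p = 0.0238) within the plain series, and 0.31, 0.19 and 0.46 within the G series (exact p between 0.143 and 0.429). Cell cycle genes came nearest to passing, with a difference of 0.31 (exact permutation p = 0.00591, adjusted p = 0.142), 0.44 within the plain series (5 against 4, exact p = 0.0238) and 0.13 within the G series (3 against 4, exact p = 0.40). No list passed. The edgeR test called 0 genes, with 1243 at unadjusted p under 0.05, and DESeq2 called 11, namely Rab4a, Sult1e1, Mgp, Spon1, Baiap2l1, Gja5, Kcnt1 and the Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y.

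The interaction of transgene and Sipa1l2 genotype asked directly whether the transgene's effect differed between both backgrounds, and no gene passed by edgeR. The genes with the smallest p-values included Fam110c (log2 interaction 2.48 ± 0.66, SE, adjusted p = 0.70) and Kif7, a kinesin of Hedgehog signalling (0.73 ± 0.19). Pmp22 had an interaction of -0.40 ± 0.40, Mbp -0.31 ± 0.40, Egr2 -0.46 ± 0.48, Sox10 -0.15 ± 0.46 and Sipa1l2 -0.15 ± 0.33. Jun had 0.15 ± 0.19 and Ngfr -0.27 ± 0.34, and adjusted p of these genes was at least 0.783. All 26 myelin genes had negative interactions, and 1 passed when adjusted over the list alone, as did 1 positive interaction among 24 cholesterol genes. The edgeR test called 0 genes, with 987 at unadjusted p under 0.05, and DESeq2 called 3, the Y-linked genes Kdm5d, Uty and Ddx3y. The 95% interval of an interaction had a median half-width of 0.44, and in simulated data 23.9% of 1.5-fold, 67.2% of 2-fold and 89.4% of 4-fold interactions were recovered.

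The interaction of transgene and labelled sex asked whether the transgene's effect differed between females and males, and again no gene passed by edgeR. The smallest p-values belonged to the heparan sulfate enzyme gene Ndst3 (1.98 ± 0.45, SE, adjusted p = 0.673), the orphan receptor gene Gpr173 (0.76 ± 0.18) and Trove2, which encodes the Ro RNA-binding protein (0.59 ± 0.15). Pmp22 had 0.77 ± 0.39, Mbp 0.68 ± 0.39, Sox10 0.60 ± 0.46, Egr2 0.28 ± 0.50 and Sipa1l2 0.43 ± 0.33. Jun had -0.48 ± 0.17 and Ngfr 0.60 ± 0.33, and adjusted p of these genes lay between 0.673 and 0.851. The edgeR test called 0 genes, with 1012 at unadjusted p under 0.05, and DESeq2 called 4, the Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y, which C3-PMP22 7 and 8 carried under female labels. All 26 myelin genes and all 13 myelin transcription factors had positive interactions, with medians of 0.72 and 0.22, and 0 of them passed when adjusted over the list alone. A positive value is a higher transgene effect in males. The myelin value joins unlike genotypes, since female minus male myelin scores were 0.13 in C3-PMP22 and -1.57 in the double mutant, where sex and series coincide. In simulated data 17.9% of 1.5-fold, 55.2% of 2-fold and 81.8% of 4-fold interactions were recovered.

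Within the double mutant, the 5 females and 3 males stood apart in many nerve transcripts. Myelin genes scored -0.93 ± 0.40 (SD, n = 5) in females and 0.64 ± 0.11 (n = 3) in males (exact permutation p = 0.0179, the smallest possible, adjusted p = 0.0357). Pmp22 lay at 10.17 ± 0.44 log2 CPM (n = 5) in females and 11.90 ± 0.05 (n = 3) in males, and Mbp at 11.34 ± 0.51 and 12.92 ± 0.20. Nefm lay at 1.02 ± 0.76 and 2.68 ± 0.24, and Sipa1l2 at 5.84 ± 0.32 and 7.03 ± 0.23 log2 CPM. Repair Schwann cell scores were -0.06 in females and 0.51 in males, and macrophage scores 0.48 and -0.16. Over 24 lists, 12 reached an exact p of 0.0179 and adjusted p = 0.0357. Adipocyte scores were among these, at 0.40 ± 0.36 (SD, n = 5) in females and -0.67 ± 0.23 (n = 3) in males, with 0.60 ± 0.39 and -0.32 ± 0.13 for fatty acid synthesis and 0.47 ± 0.35 and -0.29 ± 0.29 for lymphocytes. The skeletal muscle score was 2.41 ± 0.89 in the females and -1.28 ± 5.47 in the males. Since all 5 females carried plain numbers and all 3 males G numbers, sex and series cannot be told apart in this genotype.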

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

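The tests of C3-PMP22 7 and 8, of Sipa1l2 and of the female double mutants and the bound on other splits for C3-PMP22 against WT were chosen after the results were seen, as were the pooled and shared counts themselves, while the bounds on their splits and on those of the other comparisons were set before.

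C3-PMP22 7 and 8 were labelled female and carried Y-linked transcripts. A mixture of female and male tissue is argued against by Xist, whose higher value of 0.366 CPM in these libraries lies under the 0.964 CPM of the highest labelled male library and far under the 888.3 CPM of the lowest matching female one. Sex labels exchanged with labelled male libraries of the series would need such libraries without Y-linked transcripts, and there were 0. Libraries exchanged with non-transgenic ones are argued against by Ankrd63, whose lower value of 3.05 CPM exceeds the 1.18 CPM of every non-transgenic library. A wrong sex label, or an exchange with a transgenic male from outside the series, may account for both libraries and was not tested, and no biological explanation was tested.

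Sipa1l2 counts were not lower in libraries labelled Sipa1l2-/- over both sexes. Columns in an order unrelated to the samples are unlikely to account for this, since 30 of 32 libraries matched the labelled sex (exact hypergeometric p = 2.40e-07). Exchanges within a sex between libraries labelled Sipa1l2-/- and others stay open, since sex-linked genes cannot show them. If the genotype labels followed the locus, genes near it might differ between the groups. Of 120 genes within 10 Mb, 14 (11.7%) had an unadjusted p under 0.05 against 6.72% elsewhere (Fisher's exact one-sided p = 0.0318), and 4.47% of windows of that size held as high a share, so labels unrelated to the locus cannot be told apart from labels that follow it. Of these 14, Ttc13 (-0.23), Trim67 (-1.20), Gm16163 (-1.06), Gnpat (-0.27) and Sprtn (-0.27) lay together beside Sipa1l2, between 124671332 and 124906161. All of these were lower over both backgrounds, while Plcg2, Cbfa2t3, Sult5a1 and Irf2bp2 were higher. The edgeR adjusted p of the 14 was at least 0.492, and the grouping of lower genes was not tested. Rab4a (chromosome 8, 123805985 to 123835287) was also among the 14, at -0.34 over both backgrounds (unadjusted p = 0.00277). It had the smallest p between double mutant and C3-PMP22 (-0.66, edgeR adjusted p = 0.601, DESeq2 adjusted p = 0.0317), which goes with labels that follow the locus, but -0.014 between Sipa1l2-/- and WT. The bound for this test was moved from 5 to 1 percent of windows after the value was seen. An allele that removes the protein and leaves the transcript in place stays open, since counts per gene cannot show it.

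Myelin transcripts were lower in female than in male double mutants. The effect against WT differed between the sexes by an exact permutation of labels within sex, with a difference of differences (females minus males) of -1.63 for myelin proteins and lipids (adjusted p = 0.00952). It was -0.77 for myelin transcription factors (adjusted p = 0.0119), 0.49 for ER stress genes (0.00952), -0.67 for neuropathy genes (0.0152) and -0.45 for the SIPA1 family (0.00952). This permutation is exact only if genotype has no effect in either sex. Its p-values are therefore approximate for a difference between the sexes. Females and males differed by -1.57 in the myelin score. A series difference common to all genotypes is argued against by WT, where plain minus G numbers gave 0.35 (95% confidence interval -0.30 to 1.00, 3 against 4), and by C3-PMP22, where they gave 0.23 (-0.45 to 0.91, 4 against 4). Sipa1l2-/- went the other way, at -0.80 (-1.46 to -0.13, 7 against 2), so the value of -0.0345 over the 3 genotypes (-0.42 to 0.35, 24 libraries) joins opposite directions. A series difference in libraries labelled Sipa1l2-/- therefore stays open. Dilution by other tissue would lower all nerve transcripts alike, perineurial ones included. The perineurial score differed by -0.24 (-0.78 to 0.30), and its lower end only just cleared the bound, a fixed share of the myelin difference. Scores of repair (-0.57) and non-myelinating Schwann cells (-0.91) and of axonal genes (-0.94) were lower in the females too. The perineurial score thus argues only weakly against dilution as the whole source of the pattern. Dilution as part of it stays open, since adipocyte scores were higher in the females by 1.08, fatty acid synthesis scores by 0.91 and lymphocyte scores by 0.75. With labels as given, female minus male myelin scores were 0.06 in WT, -0.12 in Sipa1l2-/- and 0.13 in C3-PMP22 (exact permutation p between 0.629 and 0.886). These values argue against a sex difference as large as -1.57 that is common to all genotypes. With 3 to 5 libraries of each sex, a smaller common difference stays open. In C3-PMP22 the value also rests on libraries 7 and 8, which carried Y-linked transcripts under female labels. An effect of sex in the double mutant alone and a difference specific to the series of these animals could each account for the pattern. Sex and series cannot be told apart, because every female double mutant carried a plain and every male one a G number. Most female double mutants also shared the leading part of their number, which no WT library carried. What that part stands for is not given, and a difference tied to it was not tested. The permutation tests treat these females as independent.

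Other splits of the same libraries tested whether chance gives as many calls, with 100 splits for each. For C3-PMP22 against WT the real 106 calls were reached in 3 splits, the real one included, with a highest other of 1807. That share lies under the level of 0.05, but 100 splits measure it only roughly, so chance is unlikely rather than excluded. For the double mutant the real 213 against WT were reached in 3 (highest other 826) and the real 111 against Sipa1l2-/- in 2 (highest other 237), so the same holds there. For the pooled transgene contrast the real 512 were reached in 1, the real split (highest other 1), and for the 48 shared calls in 1 (highest other 0). For results of 0 the splits decide nothing, since each of the 100 gives at least 0 calls: Sipa1l2-/- against WT (highest other 5), double mutant against C3-PMP22 (14), the interactions of the transgene with Sipa1l2 (1581) and with sex (246), and the pooled Sipa1l2-/- contrast (1720). Splits that called many more genes than the real one point to a structure of the samples, but no test linked the number of calls to any measured structure. The split with 1807 calls set apart muscle scores by 4.36 and that with 1720 by -4.66. The split with 826 calls held 6 G libraries against 1 and set apart myelin scores by 1.06. For the interaction splits with 1581 and 246 calls, what set the libraries apart was not measured as a difference of differences. With a series term, 104 of 106 calls between C3-PMP22 and WT were kept and 163 of 213 between double mutant and WT. All 106 and all 213 kept their sign, with median ratios of log2 fold changes of 0.999 and 0.983.

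A sample stood far from the rest of its group in 18 of 336 groups of values, in 13 libraries, where chance marks about 5 percent, or 1 in 20. Each value is the gap to the nearest library as a share of the group's range. In WT it was 0.616 for the total count of WT 1, 0.604 for the myelin transcription factor score of WT 2, 0.687 for the immediate early score of WT 7 and 0.675 for Sncg in WT 1. In Sipa1l2-/- it was 0.516 for a further gene in library 8, 0.511 for Slc1a4 in library 7 and 0.523 for Col4a2 in library 7. In C3-PMP22 the scores gave 0.630 for fatty acid synthesis in library 3, 0.561 for repair Schwann cells in library 7, 0.527 for immediate early genes in library 4 and 0.608 for neuropathy genes in library 5. Genes there gave 0.535 for Ppp2r2c and 0.734 for Emid1 in library 6, 0.693 for Tubb3 and 0.681 for Nefh in library 5, and 0.662 for Aif1 in library 1. In the double mutant it was 0.763 for the skeletal muscle score of library 7 and 0.537 for a further gene in library 3.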

How the results depend on the processing

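Robust estimation, sex from sex-linked genes, C3-PMP22 7 and 8 left out, terms or trends for series, muscle and adipocyte scores, single libraries left out of scores, and all settings of the pooled and shared counts were chosen after the results were seen, and the others before. Over settings other than single libraries, values of named genes kept direction and side of the threshold in 2876 cases, lost their call in 115, gained one in 15 and reversed in 2. List scores kept both in 1251, lost a call in 7 and gained one in 57. With single libraries left out these were 4480, 157 and 3 for genes and 3806, 28 and 6 for scores. Gene counts stayed within 1.5 times under DESeq2's size factors, both filters, the compared groups alone, robust estimation and terms for sex-linked sex, series or muscle. Depth limits genes below the filter, which were not tested. Where no cause is given below, the cause was not tested.

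The DESeq2 Wald test called 375 genes for C3-PMP22 and 499 for the double mutant against WT, 11 for double mutant against C3-PMP22, 219 against Sipa1l2-/-, 3 and 4 for the interactions with Sipa1l2 and sex, 846 and 12 for the pooled transgene and Sipa1l2-/- contrasts, and 98 shared. Total counts only gave 118 and no sex term 134 for the double mutant against WT. With C3-PMP22 7 and 8 left out, C3-PMP22 against WT had 58 calls (58 robust), with fewer samples, and Ddx3y reversed to -0.0497 in both fits because both libraries carry its reads. Muscle and adipocyte score terms gave 172 for C3-PMP22 and 938 for the double mutant against WT, 252 against Sipa1l2-/-, 816 pooled transgene and 102 shared, and 172, 933, 244, 814 and 100 with robust estimation.

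Among lists, C3-PMP22 against WT had 1 with total counts only, 1 for members with mean CPM of at least 1, 1 with the mean of each animal-number series removed and 1 with camera, estimated correlation. Camera, preset correlation 0.01, called 11 there, 4 for Sipa1l2-/- against WT, and 15, 12 and 12 for the double mutant against WT, C3-PMP22 and Sipa1l2-/-. Camera, estimated correlation, called 0 for the double mutant against WT and 1 against Sipa1l2-/-. Against WT the double mutant had 1 with the trend on the muscle score removed. Against Sipa1l2-/- it had 1 with prior count 0.5, 1 with the mean of each sex removed, 2 with the mean of each animal-number series removed and 1 with the trend on the muscle score removed.

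Leaving out single libraries gave 71 to 410 calls for C3-PMP22 and 111 to 297 for the double mutant against WT, 84 to 141 against Sipa1l2-/-, 391 to 673 for the pooled transgene contrast and 41 to 61 shared. The pooled Sipa1l2-/- contrast had 0 to 2, with 1 without C3-PMP22 1, 1 without Sipa1l2-/- 7 and 2 without WT 4. Sipa1l2-/- against WT, double mutant against C3-PMP22 and both interactions had 0 to 0. Lists ranged from 1 to 3, 0 to 3 and 0 to 2 for C3-PMP22 and the double mutant against WT and the double mutant against Sipa1l2-/-, and 0 to 0 otherwise.

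The sample number as a block gave 123 and 309 calls for C3-PMP22 and the double mutant against WT, 94 against Sipa1l2-/- and 0 elsewhere. The numbers showed little sign of pairing the libraries. The 45 pairs of equal number had a median correlation of deviations of 0.090, against -0.002 for pairs of different number. Their range was -0.56 to 0.74, with 22 pairs over 0.1, and in 7 libraries the best partner carried their number.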

Other observations

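The pooled transgene contrast and the position scan were chosen after the results were seen. With both transgenic genotypes (n = 16) set against both others (n = 16), edgeR called 512 genes, 243 higher and 269 lower, among 2648 at unadjusted p under 0.05, and 370 of the 512 calls were kept with a muscle score term and 363 without C3-PMP22 7 and 8. All 512 kept their sign in both settings, with median ratios of log2 fold changes of 0.965 and 0.999. With scaling by total counts alone 404 genes were called, 117 higher and 287 lower, so the balance of directions depended on the scaling. List members named below were limited to calls kept without C3-PMP22 7 and 8 and in at least 30 of the 32 fits that leave out 1 library, a choice made after their values were seen. Of 24 cholesterol biosynthesis genes 16 fell, among them Idi1 (log2 fold change -0.47 ± 0.11, SE, adjusted p = 0.0120) and Fdps (-0.47 ± 0.10, adjusted p = 0.00704). Of 18 repair Schwann cell genes 7 rose, including the neurotrophic factor gene Gdnf (1.44 ± 0.30, adjusted p = 0.00390), the transcription factor gene Runx2 (0.74 ± 0.15, adjusted p = 0.00448) and the peptide gene Ucn2 (2.14 ± 0.43, adjusted p = 0.00282), while the cytokine gene Lif fell (-0.66 ± 0.15, adjusted p = 0.00900). Gdnf and Ucn2 had means under 1 CPM over all libraries, so their fold changes rest on few counts. Pou3f1, a transcription factor of promyelinating Schwann cells, rose (1.19 ± 0.25, adjusted p = 0.00469). No myelin protein and lipid gene was called among 26. Against WT of the same labelled sex, the myelin score differed by -1.06 in female and 0.57 in male double mutants, so the pooled value joins opposite directions. It differed by 0.13 and 0.05 in C3-PMP22.

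Of 13 axonal and neuronal genes 8 fell and 1 rose with the transgene in that contrast. The fall was uneven over the transgenic libraries. Against WT of the same labelled sex, axonal scores differed by -0.75 in female and -0.02 in male double mutants. They differed by -0.08 in female and -0.61 in male C3-PMP22 libraries. The neurofilament genes Nefm (-0.87 ± 0.23, adjusted p = 0.0289) and Nefh (-0.96 ± 0.24, adjusted p = 0.0200) fell, as did the peptide gene Calca (-0.81 ± 0.19, adjusted p = 0.0153), and Tubb3 rose (1.59 ± 0.30, adjusted p = 0.00140). Of 23 macrophage genes 5 rose, among them Ms4a7 (0.80 ± 0.17, adjusted p = 0.00451) and Lgals3 (0.53 ± 0.10, adjusted p = 0.00102). Of 10 genes of the SIPA1 family list, which also holds Rap GTPases and their regulators, 1 rose, the regulator Rap1gap, which inactivates the GTPase RAP1 (0.91 ± 0.23, adjusted p = 0.0248). Its adjusted p was 0.0517 without C3-PMP22 3, 0.0504 without WT 5 and 0.0607 with total counts alone, and that of Nefm was 0.0559 without WT 2. With terms for sex-linked sex, series and muscle together, adjusted p was 0.0708 for Rap1gap and 0.0729 for Calca. Chosen after their values were seen, the growth factor gene Igf2 fell (-0.82 ± 0.08, adjusted p = 2.08e-07) and Tyrp1, a gene of melanin synthesis, rose (4.53 ± 0.50, adjusted p = 6.83e-07). Tyrp1 had a mean under 1 CPM over all libraries, so its fold change rests on few counts. Between libraries labelled Sipa1l2-/- and the others, 0 genes passed over both backgrounds by edgeR (1044 at unadjusted p under 0.05), and DESeq2 called 12, among them Adamdec1, Mall, Mgp, Plod2, Cdkl4, Adamtsl2, Mab21l1, Gja5 and the Y-linked genes Kdm5d, Uty and Ddx3y.

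Genes that differ with the transgene may lie around a single locus, as a transgene insertion with flanking sequence of another strain would give. Of 508 calls with a position, at most 8 lay in a window of 5 Mb, on chromosome 10, and a share of 0.921 of 1000 random sets of as many genes had as many in a window. The test argues against calls gathered around a single locus as a source of most calls, and a few genes at one locus stay possible.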
